A study of Mus musculus with 9 samples.

How the data were processed

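RNA from C2C12 cells, a mouse skeletal muscle cell line, was measured on 9 Affymetrix oligonucleotide arrays after 5 days in differentiation medium. The arrays were of 3 designs, U74Av2, U74Bv2 and U74Cv2, with 3 replicates of each. The designs carry different probe sets, apart from 66 control probe sets that all 3 designs share. The groups used here are the array designs, since the labels give a single condition and no untreated sample. Per the labels, all arrays carry the same sample identifier and the same RNA concentration of 2 ug per ul. The labels do not say that the replicates came from separate cultures, so the spread between them may be technical, and each p-value measures only the spread between these arrays or a contrast between sets of genes.

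The deposited values are probe set intensity on a linear scale, made by the authors with MAS5, per the submitters' processing notes; the version and settings are not given in the sources used here. A 2% trimmed mean computed on each array lay between 1500.3 and 1501, so the values had been scaled to a common level on each array. Scaling was done on each array by itself, so signals of different designs share a trimmed mean but not a normalization. Detection calls were not used here. Each array's instrument settings gave the chip type, which matched the label on all 9 arrays, and the fluidics station. The arrays of each design had been scanned on a day of their own, so design and day cannot be told apart. On U74Bv2 and U74Cv2, replicate 1 was washed on another station than replicates 2 and 3, and on U74Cv2 it was also of another chip lot.

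A background limit was computed for each array as the 95th percentile of its control probe sets for sequences absent from the sample. These were the Dap, Lys, Phe, Thr and Trpn controls and the reverse-strand controls, leaving out each family whose median lay above the design's median signal. That left 20 control probe sets on U74Av2, 20 on U74Bv2 and 17 on U74Cv2. A probe set counted as detected when it lay above the limit on all 3 arrays of its design. Control probe sets were left out of all counts of detection.

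Gene symbols came from the platform annotation. On U74Av2, 10833 probe sets had 1 symbol, 396 had several and 1193 had none. The same counts were 10581, 178 and 1652 on U74Bv2, and 7717, 150 and 4001 on U74Cv2. Of the Entrez identifiers, 99.7% were found in the RefSeq gene table of the mouse assembly GRCm38.p6, and 0 symbols needed an update. No coordinates are given, since the sources name no genome build. Only probe sets with 1 symbol named a gene, which gave 15964 genes. A gene counted as detected when at least 1 of its probe sets was detected. A gene's signal is that of its probe set with the highest mean signal, whatever its design. The shared control probe sets read higher on U74Bv2 and U74Cv2 than on U74Av2, so this choice may favour probe sets of those designs. The multiples of the limit rest on it, and so do the list spreads, which used detected probe sets only. For the signal percentiles of the lists, the probe set with the highest mean percentile within its arrays was taken instead. For Kdr the choice by mean signal fell on a U74Cv2 probe set at 0.47 times the limit, which was not detected, although another was. A signal depends on the affinity of the probes as well as on the RNA, so signals are not compared from gene to gene and are mostly given as multiples of the background limit.

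The gene lists, the panel of 34 genes, the tests, the rule for named genes and all alternatives except 4 entries added later were fixed before the data were examined. There were 34 lists with 960 entries, of which 850 were measured. The lists covered 10 parts of the muscle programme, 14 cell states and 10 other cell types. Each list was compared with all other measured genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 34 lists. Genes are not replicates, so these p-values describe these arrays. The median signal percentile of each list was set against 10000 random lists of the same size and the same split over designs. The replicate spread of each list, as the median SD of log2 signal over its detected genes, was set against 10000 random lists matched on design and on mean signal in 20 bins. A list stood apart when it lay below the 2.5th or above the 97.5th percentile, with no adjustment for the number of lists.

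The 66 shared control probe sets were compared between designs with limma 3.58.1 in R 4.3.3, as a moderated F-test on log2 signal with Benjamini-Hochberg adjustment and a threshold of 0.05. Agreement between probe sets of one gene was set against 10000 random reassignments within designs. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The genes to be named were the panel genes, up to 3 detected genes with the highest signal in each list, and the 5 genes with the highest signal and with the largest spread on each design. These were 144, and the text names only part of them, a selection made after the values were seen. Genes of a list that were not detected are named where they are few, and those names were chosen after the values were seen.

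The tests were tried on simulated data. In the simulation of list detection over 15964 genes, 96% of lists of 20 genes with 95% of members detected against a base of 60% were found, and 4% of unchanged lists were called. For replicate spread over the same number of genes, 80% of lists with a 1.6-fold larger SD were found, and 2% of unchanged lists were called. In both simulations every unchanged gene had the same base share or the same SD, whatever its probe set number, design or signal. The rates of false calls in the real lists may therefore differ from these. For the 66 shared control probe sets, limma found 98.75% of simulated shifts of 2 on the log2 scale, 20.5% of shifts of 1 and 1.25% of shifts of 0.5. At a shift of 2, 2.28% of the unshifted probe sets were called. All probe sets had the same SD there, and only part of them were shifted, in a single design. No shift was common to a whole array, so the rates in the real data may differ. Alternatives covered the background limit, the number of arrays needed, each replicate left out, the designs and probe sets used, random lists matched on probe set number and design, quantile normalization, and log2 of the signal plus 16. The number of arrays, 3 for each design, limits the precision of every signal.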

Results

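C2C12 is a line of mouse skeletal myoblasts that leave the cell cycle and fuse into multinucleate myotubes when serum is lowered. The cells had been kept for 5 days in differentiation medium with 2% horse serum at 37 °C, and their total RNA was hybridised to 9 arrays, 3 of each of 3 designs. With one condition and no undifferentiated cells, the arrays show which genes gave signal in differentiated cells and how closely the replicates followed one another. They do not show which genes changed on differentiation.

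On U74Av2, 7225 of 12422 probe sets (58.2%) were detected, that is, lay above the background limit on all 3 arrays. The count was 5437 of 12411 (43.8%) on U74Bv2 and 3752 of 11868 (31.6%) on U74Cv2. The background limit was 206, 280 and 256 signal units on the U74Av2 arrays of replicates 1, 2 and 3. It was 498, 430 and 963 on the U74Bv2 arrays and 1034, 725 and 786 on the U74Cv2 arrays. On single arrays, between 4376 and 8257 probe sets lay above the limit. With the array's median signal as the limit, 5785, 5381 and 4671 probe sets were detected on U74Av2, U74Bv2 and U74Cv2. Without replicate 3, 6998 were detected on U74Bv2. The size of the fall from design to design thus depends on the limit. Of 15964 genes named by a probe set, 9891 (62.0%) were detected.

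The first question was whether the muscle programme gave signal in these cells. Myogenin (Myog, 103053_at), a transcription factor of early muscle differentiation, had a signal of 16210 ± 294 (SD, n = 3), 66.7 ± 11.7 times the background limit. Myod1 (102986_at), a myogenic determination factor, lay at 31.7 ± 4.1 times the limit and Myf5 (101162_at) at 7.0 ± 0.7 times (SD, n = 3). Myf6, a factor of later muscle, was not detected, with a signal of 66.3 ± 19.8, 0.28 ± 0.12 times the limit (SD, n = 3). Mef2c, a partner of the myogenic factors, lay at 5.9 ± 2.4 times the limit of U74Bv2, and 6 of its 7 probe sets were detected. Of the list of myogenic transcription factors, 16 of 19 measured genes (84.2%) were detected, and Eya2, Eya4 and Myf6 were not. That share did not pass the threshold against other genes (adjusted p = 0.0646, Fisher's exact test).

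Contractile genes were detected for developmental, slow and fast isoforms alike. Skeletal alpha-actin (Acta1, 100381_at) had a signal of 73080 ± 5872 (SD, n = 3), 298 ± 31 times the limit, and cardiac alpha-actin (Actc1, 101029_f_at) lay at 209 ± 42 times. Embryonic myosin heavy chain (Myh3) lay at 36.0 ± 7.8 times the limit, perinatal Myh8 at 5.9 ± 2.0 times, slow Myh7 at 56.9 ± 16.3 times and fast Myh4 at 8.9 ± 1.7 times (SD, n = 3). Fast Myh2 was not detected, at 0.23 ± 0.13 times. Myl4, an embryonic myosin light chain, lay at 138 ± 16 times, cardiac troponin T (Tnnt2) at 80.5 ± 13.0 times, desmin (Des) at 15.9 ± 2.8 times and caveolin 3 (Cav3) at 14.6 ± 3.9 times (SD, n = 3). The probe sets of Actc1, Myh7, Myh8, Cav3 and Tnni1 carry a suffix that marks possible cross-hybridisation, so their signal may include that of related genes. Among the genes named below, the same holds for Atp2a1, Ckm, Cox6c, Aldoa, Rpl41, Mcl1, H2-D1, Pparg, Igf2, Mki67, Lefty1, Tubb3, Sox9 and 1700113H08Rik. Slow and developmental isoforms were detected for 16 of 17 genes (94.1%, adjusted p = 0.0102, Fisher's exact test), with Myl3 as the exception. Fast and adult isoforms were detected for 14 of 16 genes (adjusted p = 0.0473), and Myh2 and Myoz1 were not. Of the thin filament and Z disc, 23 of 27 genes were detected (adjusted p = 0.0252), among them Tnni1 at 142 ± 24 times the limit of U74Cv2. Actn2, Myot, Myoz1 and Tnni3 of that list were not detected. Of the thick filament, 14 of 17 genes were detected (adjusted p = 0.135), and Myh2, Myh6 and Myl3 were not. These lists share members, since each of the 17 slow and developmental genes and 15 of the 16 fast ones also stand in another list.

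Genes of calcium release and of fusion were detected nearly throughout. Of the calcium handling and triad genes, 20 of 21 (95.2%) were detected, all but Pln (adjusted p = 0.00469, Fisher's exact test). Atp2a1, the calcium pump of fast fibres, lay at 55.8 ± 13.1 times the limit, Ryr1, the calcium release channel, at 11.6 ± 3.4 times, and Bin1, which shapes the T-tubules, at 132 ± 19 times (SD, n = 3). Of the genes for myoblast adhesion and fusion, 22 of 24 (91.7%) were detected (adjusted p = 0.00668), and Elmo1 and Itga4 were not. Mymk (107099_at), the fusion protein myomaker, had a signal of 56429 ± 6533 (SD, n = 3), 104 ± 46 times the limit of U74Bv2. Cdh15, M-cadherin, lay at 19.7 ± 1.9 times the limit.

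Subunits of the acetylcholine receptor were among the detected genes of the neuromuscular junction, 14 of 16 (adjusted p = 0.0473, Fisher's exact test). The fetal subunit Chrng lay at 33.2 ± 8.7 times the limit and Chrna1 at 21.5 ± 4.1 times (SD, n = 3), while Ache and Musk were not detected. Of the dystrophin complex and costamere, 17 of 21 genes were detected (adjusted p = 0.12). Dmd, the dystrophin gene, Sgcd, Sntb2 and Synm were not detected, and the probe set of Dmd (93623_at) lay at 0.068 ± 0.026 times the limit (SD, n = 3). Of genes of the satellite cell and myoblast state, 21 of 25 were detected (adjusted p = 0.0357). Id1, an inhibitor of the myogenic factors, lay at 4.7 ± 1.0 times the limit. Pax3 lay above the limit on only 2 of 3 arrays, at 1.2 ± 0.8 times (SD, n = 3), and Calcr, Fgfr4 and Id4 were not detected either. The panel genes Pax7, Ccnb1 and Runx2 were not analysed here.

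**Figure D1:**
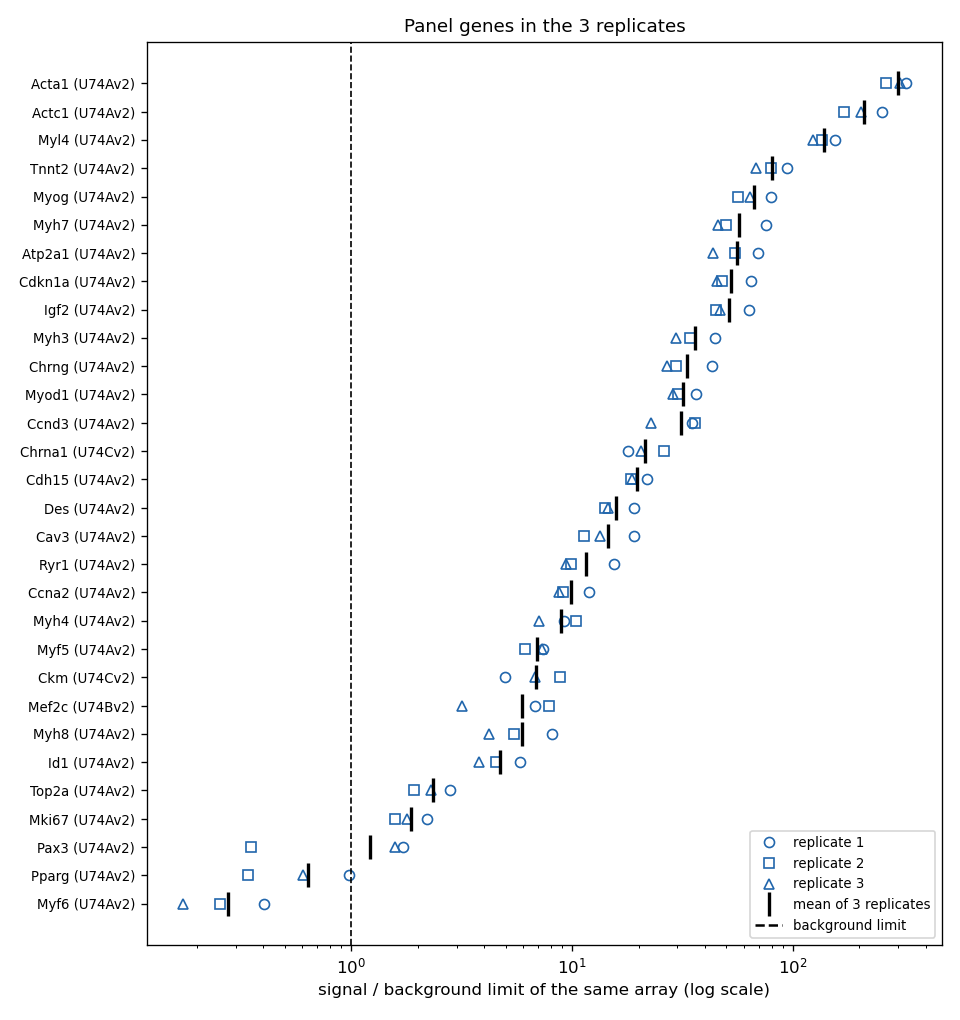
Signal of each measured panel gene divided by the background limit of the same array (log scale), with 1 symbol for each of the 3 replicates and a bar at their mean. Acta1 lay at 298 times the limit, while Myf6 and Pparg lay below it on all 3 arrays and Pax3 below it on 1 array.

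The next comparison concerned the state of the cells. Transcripts of cell cycle inhibitors and of mitotic genes were detected side by side. Cdkn1a (94881_at), the cyclin-dependent kinase inhibitor p21, had a signal of 12730 ± 1011 (SD, n = 3), 52.4 ± 10.6 times the limit. Ccnd3 lay at 31.2 ± 7.3 times, with 1 of its 3 probe sets detected. Of the cell cycle exit genes, 18 of 21 were detected (adjusted p = 0.0363, Fisher's exact test), and Ccnd2, Cdkn2a and Cdkn2b were not. Of the genes of G2 and M phase, 35 of 36 (97.2%) were detected, all but Bub1 (adjusted p = 1.64e-05). Ccna2 lay at 9.9 ± 1.7 times the limit, Top2a at 2.3 ± 0.4 times and Mki67 at 1.9 ± 0.3 times (SD, n = 3). Mki67 was detected by 1 of its 2 probe sets, whose signal lay below the array's median signal on all 3 arrays. The median signal percentile of the G2 and M phase list was 66.7, which was not apart from random lists. Of the S phase genes, 25 of 32 were detected (adjusted p = 0.0749).

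Energy metabolism and protein turnover were well represented. Of the genes of oxidative phosphorylation, 43 of 45 (95.6%) were detected (adjusted p = 7.97e-06, Fisher's exact test), all but Cox7a1 and Cox8a, and Cox6c lay at 129 ± 17 times the limit (SD, n = 3). Glycolysis and glycogen genes were detected in 22 of 26 cases (adjusted p = 0.0252), with Aldoa at 166 ± 27 times the limit. Fatty acid and creatine metabolism gave 24 of 28 genes (adjusted p = 0.0181). Ckm, the muscle creatine kinase, lay at 6.9 ± 1.9 times the limit of U74Cv2, and all 4 of its probe sets were detected. Of the proteasome and muscle ubiquitin ligase genes, 27 of 30 were detected (adjusted p = 0.00469), among them Psmc6 at 80.3 ± 6.6 times. Of the ribosomal proteins, 28 of 35 were detected (adjusted p = 0.0457), and Rpl41 lay at 351 ± 71 times the limit.

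Stress and growth factor genes followed. Immediate early genes were detected in 24 of 25 cases (96.0%, adjusted p = 0.00106, Fisher's exact test), all but Klf2, and Jund lay at 144 ± 7 times the limit (SD, n = 3). Of the heat shock and unfolded protein response genes, 33 of 35 were detected (adjusted p = 0.000306), all but Calr and Hspb1. Hsp90aa1 lay at 98.3 ± 16.3 times the limit. Insulin-like growth factor signalling gave 21 of 23 genes (adjusted p = 0.00668), and Igfbp1 and Igfbp3 were not detected. Igf2 had probe sets that differed, with 98623_g_at at 51.6 ± 10.0 times the limit and 98622_at at 0.24 ± 0.04 times (SD, n = 3). Extracellular matrix genes were detected in 42 of 50 cases (adjusted p = 0.00469), with Col5a2 at 170 ± 23 times the limit. Caspases and apoptosis regulators gave 28 of 35 genes (adjusted p = 0.0457), with Mcl1 at 20.2 ± 1.0 times the limit of U74Cv2. The interferon response was the one cell state detected less often than other genes, with 12 of 34 (35.3%, adjusted p = 0.00668). Its detected members included B2m at 106 ± 7 times the limit and H2-D1 at 23.2 ± 4.6 times, while Isg15, Mx1 and Ifit1 were not detected.

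Markers of other cell types were mostly not detected. Bone and cartilage markers were detected in 2 of 13 cases (15.4%, adjusted p = 0.00469, Fisher's exact test), namely Ihh and Sox9. Ihh lay near the limit, at 1.8 ± 0.4 times (SD, n = 3). Endothelial markers gave 4 of 17 (adjusted p = 0.00662), namely Egfl7, Eng, Kdr and Pecam1. Liver markers gave 5 of 19 (adjusted p = 0.00766), epithelial and skin markers 7 of 22 (adjusted p = 0.0134), and pluripotency and germ cell markers 8 of 25 (adjusted p = 0.00766). Blood and immune cell markers gave 9 of 27 (adjusted p = 0.00998) and adipocyte markers 5 of 15 (adjusted p = 0.0441). Pparg, a regulator of fat cells, lay at 0.64 ± 0.32 times the limit and was not detected (SD, n = 3). Neuron and glia markers gave 9 of 22 (adjusted p = 0.0571), and cardiac markers 10 of 16 (adjusted p = 1). Single members of these lists were detected, such as Epcam at 10.2 ± 2.8 times the limit, Lefty1 at 21.9 ± 4.0 times, and Tubb3, a neuronal tubulin, at 57.0 ± 11.3 times (SD, n = 3). The probe sets of Lefty1 and Tubb3 are among those open to cross-hybridisation. Smooth muscle markers went the other way, with 15 of 16 detected (adjusted p = 0.0152), all but Myocd. That share did not pass against random lists matched on probe set number and design (median 68.75%, adjusted p = 0.0616, permutation of genes). Des and Tpm2 of this list also stand in the thin filament list. Acta2, smooth muscle alpha-actin, lay at 226 ± 33 times the limit and Cald1 at 84.6 ± 32.9 times.

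**Figure D2:**
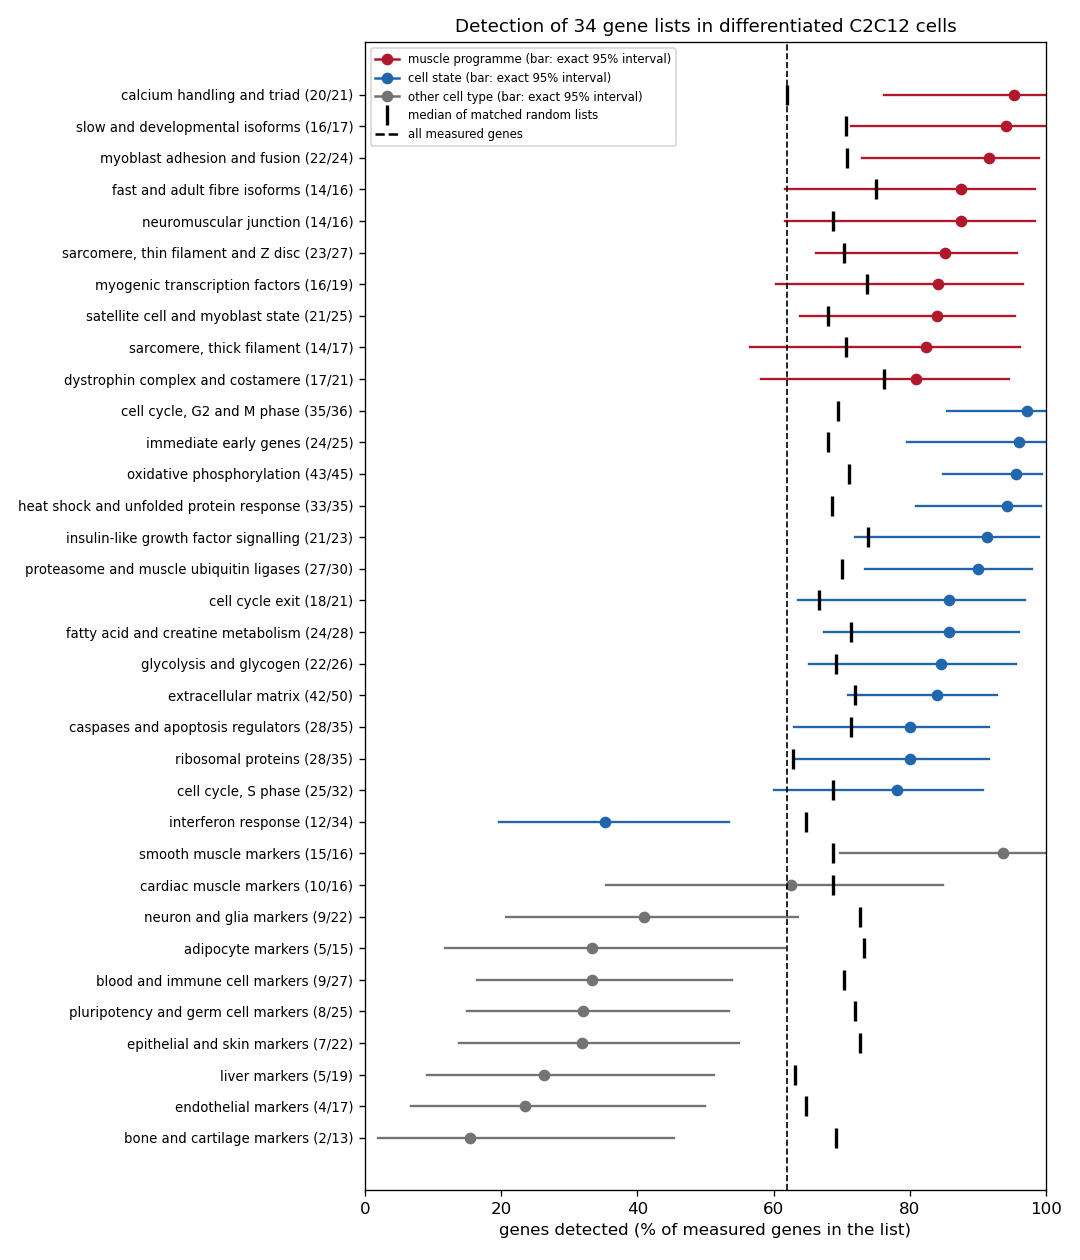
Share of measured genes detected in each of 34 gene lists (points, with exact 95% intervals as bars), coloured by kind of list, with the median share of matched random lists (short black bars) and the share of all measured genes (dashed line, 62.0%). Calcium handling genes stood at 95.2% and bone and cartilage markers at 15.4%.

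Of the 34 lists, 20 were detected more often than other genes, 8 less often, and 6 did not pass the threshold. Of the 20, 7 were of the muscle programme, 12 were cell states, and 1 was of another cell type. Random lists matched on probe set number and design had median shares between 61.9% and 76.2%. The matching counted a gene's probe sets on a design only up to a cap, so genes with many probe sets were not matched exactly. Against these, 7 lists were detected more often: calcium handling and triad, myoblast adhesion and fusion, G2 and M phase, oxidative phosphorylation, proteasome, immediate early genes, and heat shock and unfolded protein response. Against the same matched lists 9 were detected less often, the neuron and glia markers (adjusted p = 0.00309) in addition to the 8. With U74Av2 alone 7 lists were detected more often, but not the same 7. Myoblast adhesion and fusion did not pass there (15 of 17 genes, adjusted p = 0.111, Fisher's exact test). Fatty acid and creatine metabolism did (adjusted p = 0.0278, Fisher's exact test). Without replicate 3, 12 lists were detected more often.

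The signal percentile of each list was also planned, as a description. It depends on the affinity of the probes and so does not compare the levels of genes. The median member of the fast and adult isoforms lay at the 96.1st percentile of its array, that of the slow and developmental isoforms at the 94.8th, and that of the ribosomal proteins at the 98.4th. In all, 19 lists lay above the random lists of the same size and 9 below them. With the median over a gene's probe sets in place of the highest one, these counts were 14 and 8. Endothelial markers had a median percentile of 18.6 and pluripotency and germ cell markers one of 28.7. The satellite cell state (67.3), S phase (62.7), cell cycle exit (70.5) and caspase (68.1) lists did not stand apart.

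The replicates were then compared with one another. Most lists of contractile and calcium handling genes had a larger median spread between replicates than random lists of like signal. The cut on percentiles was not adjusted for the number of lists, and these lists share members. Single lists may therefore stand apart by chance. The median SD of log2 signal was 0.236 for the fast and adult isoforms against 0.127 in random lists, 0.223 against 0.138 for calcium handling, 0.178 against 0.121 for the slow and developmental isoforms, and 0.173 against 0.121 for the thin filament. The thick filament, at 0.195 against 0.132, did not stand apart. Ribosomal proteins (0.153 against 0.118), glycolysis (0.173 against 0.125) and cardiac markers (0.308 against 0.195) also lay above the random lists. In total 7 lists lay above and 0 below. The 7 ranged from the 97.56th percentile (cardiac markers) to the 99.89th (fast and adult isoforms). Without replicate 3 only the cardiac markers lay above (0.343), since the fast isoforms fell to 0.107, calcium handling to 0.0851, the slow isoforms to 0.105, the thin filament to 0.118 and the ribosomal proteins to 0.107. Without replicate 2 the cardiac markers fell to 0.0696 and no longer stood apart, nor did the thin filament at 0.144. Without replicate 1 the cardiac markers at 0.294 and the ribosomal proteins at 0.142 did not stand apart either. Glycolysis stood apart in none of these cases, with 0.147, 0.128 and 0.121 without replicates 1, 2 and 3. Quantile normalization brought the ribosomal proteins to 0.0959, within the random lists. Across all detected probe sets, the median SD of log2 signal was 0.15 on U74Av2, 0.18 on U74Bv2 and 0.24 on U74Cv2. Probe sets that were not detected had a median SD of 0.58, 0.52 and 0.67. Across probe sets, which are not independent replicates, log2 signals of array pairs correlated at 0.96 on U74Av2, between 0.91 and 0.93 on U74Bv2, and between 0.87 and 0.88 on U74Cv2.

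The direction of that spread was looked at after the spread had been seen. In replicate 3 the fast and adult isoforms lay at a median log2 deviation of -0.25 from their own means, with 10 of 14 genes below (adjusted p = 0.00396 over 99 list and replicate pairs, p = 0.0002, the smallest that 10000 matched random lists can give, as a permutation of genes). The calcium handling genes lay at -0.21, with 15 of 20 below, and the slow and developmental isoforms at -0.16, with 13 of 16 below, at the same adjusted p. The fall was not seen on all 3 designs, though the designs were not tested against each other. The contractile and calcium handling genes as 1 list lay at -0.12 on U74Av2 (51 genes) and at -0.28 on U74Bv2 (13 genes), but at 0.12 on U74Cv2 (10 genes, 3 of them below). The deviations of a gene sum to 0 over the replicates, so a fall in replicate 3 brings a rise in the others. The values of 0.15 for the fast and 0.12 for the slow isoforms in replicate 2 follow in part from that. These lists hold genes of all 3 designs, and reading replicate 3 as 1 sample across the designs is an assumption that was not established. Jph2, which ties T-tubules to the calcium store, had signals of 20068, 21437 and 12973 in replicates 1, 2 and 3. Ribosomal proteins lay at 0.13 in replicate 3, with 27 of 28 genes above their means (adjusted p = 0.0132, permutation), and this fell to 0.03 after quantile normalization. The 3 control probe sets for 18S ribosomal RNA also differed. On U74Av2 the one at the 3 prime end read 37592, 62249 and 95513 in replicates 1, 2 and 3.

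**Figure D3:**
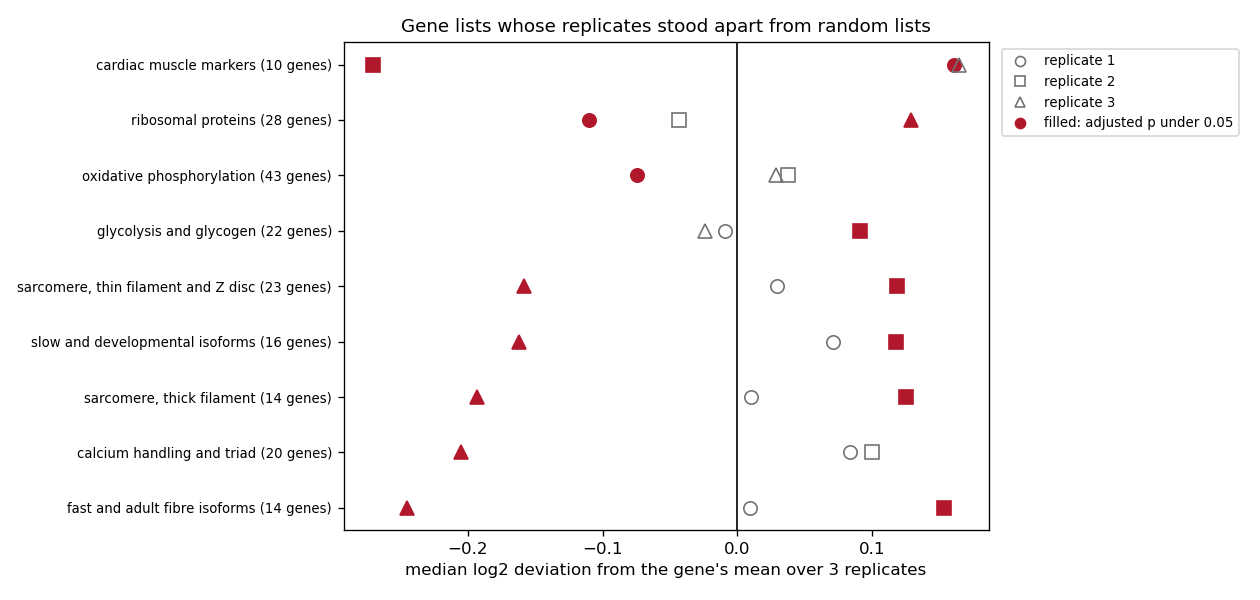
Median log2 deviation of each list's detected genes from their own means over the 3 replicates, for the 9 lists with at least 1 replicate apart from matched random lists (filled symbols, adjusted p under 0.05). The fast and adult isoforms lay at -0.25 in replicate 3 and the ribosomal proteins at 0.13.

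The control probe sets shared by the 3 designs showed how far a signal can be carried from one design to another. For these, 63 of 66 differed between designs (limma, moderated F-test, adjusted p under the threshold). All 66 were higher on U74Bv2 and on U74Cv2 than on U74Av2. The median shift was 1.34 on the log2 scale for U74Bv2, or 2.53-fold, and 2.33 for U74Cv2, or 5.03-fold, with a median SE of 0.33 for single probe sets. After each array was centred on the median of these probe sets, 0 of 66 differed by the same limma test, and 2 had an unadjusted p under the threshold.

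Detection also depended on the probe set. Of 7645 genes with at least 2 probe sets, 1658 had all of them detected, 1749 had none, and 4238 were mixed. The share in agreement, 44.6%, was above that of random reassignments, which had a median of 36.7% and a maximum of 38.9%. Examples are Kdr, the endothelial growth factor receptor, with 1 of 2 probe sets detected, and Cdh15 with 1 of 2. The largest spread among detected probe sets was found for genes such as Rnf10, with a signal of 15422 ± 10377 (SD, n = 3), and 1700113H08Rik, with 25485 ± 18253 (SD, n = 3).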

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

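The yeast controls added to the background and the centred fit with a replicate block were chosen after the data were seen. Of the values that answer a comparison, 74 stayed close to those reported and 24 moved under an alternative. The cause was not tested unless given. The tolerance for counts was wide: 14 lists detected more often, when 2 of 3 arrays sufficed, still counted as close to 20. Of the 144 named genes, 4 were no longer detected with the array median as the limit. Leaving out replicate 1 or replicate 3 changed none, and leaving out replicate 2 changed 1.

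Lists detected more often numbered 7 with U74Av2 alone, 7 against matched random lists, and 12 to 21 with a replicate left out, lowest without replicate 3. Cardiac markers, detected at 62.5% against 62.0% of other genes, passed the threshold in no setting. They stood at 62.5% without cross-hybridising probe sets and at 68.75% without replicate 2. In both of these only the sign of their log2 odds changed, from -0.01, a value computed with a small constant added to each count. The median SD of log2 signal over all probe sets was 0.240, 0.306 and 0.466 on U74Av2, U74Bv2 and U74Cv2, since these include dim ones. With a replicate left out it was 0.119 to 0.134, 0.136 to 0.158 and 0.191 to 0.204. Lists above the random lists in spread numbered 4 over all probe sets and 1 to 6 with a replicate left out, lowest without replicate 3, and lists below numbered 0 to 1. Leaving out a replicate gave calcium handling 0.0851 (without replicate 3) to 0.262 and cardiac markers 0.0696 (without replicate 2) to 0.343. Quantile normalization gave ribosomal proteins 0.0959. Probe sets of one gene agreed in 46.7% of genes when 2 of 3 arrays sufficed and in 44.4 to 45.8% with a replicate left out.

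Of the shared control probe sets, 33 of the 35 above background differed between designs, fewer because fewer were tested. After centring 0 did, and 0 with the replicate block as well (limma; 2 and 1 at an unadjusted p under 0.05). The replicate block alone gave 64. Same-numbered arrays deviated together with correlations between -0.10 and 0.53 over the shared probe sets, 8 of 9 over 0.1, and 7 of 9 correlated best with their own number. Since 1 lay below 0.1, the numbers were not taken as a pairing, though the 7 of 9 hint at one. Over genes on 2 designs the correlations lay between -0.06 and 0.06.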

Other observations

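The tests on the direction of replicate deviations and on differences between replicates, on 18S ribosomal RNA and on the medians of the arrays were chosen only after the results were seen, and the criteria for the other tests here were also written after their values were known, although the matched random lists and the splits of the arrays had been planned.

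Further lists differed between the replicates. Of 99 list and replicate pairs, 15 passed an adjusted threshold of 0.05 against matched random lists (permutation of genes). Genes of oxidative phosphorylation lay at a median log2 deviation of -0.07 in replicate 1, with 28 of 43 genes below their own means. Glycolysis and glycogen genes lay at 0.09 in replicate 2, with 17 of 22 above. Cardiac markers lay at -0.27 in replicate 2, with 7 of 10 below. After quantile normalization the medians were -0.04 for oxidative phosphorylation, 0.10 for glycolysis and glycogen and -0.26 for the cardiac markers. Among contractile genes, Ldb3 of the Z disc read 5799, 5885 and 3012 in replicates 1, 2 and 3, Tnni2 read 1331, 1465 and 916, and Myh1 read 6161, 5904 and 4439. Acta1 went the other way, with 66776, 74069 and 78395. These genes were chosen after their values were seen.

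The detected genes of 5 lists (thick filament, thin filament, fast, slow and calcium handling), 62 in all, lay at a median log2 deviation of -0.1711 in replicate 3, with 46 below their own means. Deviations sum to 0 within a gene, so the values of 0.12 in replicate 2 and 0.03 in replicate 1 follow in part from that. Taken directly, replicate 3 lay below replicate 1 by 0.18 and below replicate 2 by 0.26, both below all matched lists, and replicate 2 lay above replicate 1 by 0.08, at the 99.1st percentile. Scaling that depends on signal would be removed by quantile normalization, but this left the median at -0.19, below all matched lists. Noise of the single U74Av2 array would leave other arrays unaffected. Probe sets of 21 of these genes on U74Bv2 and U74Cv2 lay at -0.1593 ± 0.34 (SD over genes), with 12 below, at the 0.01th percentile of matched lists. That result came from U74Bv2 (-0.28 over 13 genes), while U74Cv2 showed no such shift (0.12 over 10 genes, at the 90.4th percentile). Noise of single arrays, U74Bv2 included, therefore stays open. No biological explanation was tested, because the labels name no difference between replicates.

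The 18S ribosomal RNA control probe sets were lowest in replicate 1 and highest in replicate 3 in 9 of 9 combinations of probe set and design, with a median log2 difference of 1.98 ± 0.57 (SD over the 9). The 38 other mouse control readings above the limit had a median difference of 0.07071 ± 0.29 (SD). The values had already been scaled to a common level on each array, so brightness of the whole array could hardly have shown here. The comparison shows only that 18S differed relative to the other mouse controls. Noise of single arrays would seldom give the same order on all 3 designs. The 3 probe sets of a design share its arrays, though, so the 9 combinations are not independent, and this order prompted the test. Whether a replicate number marks the same material on all designs was not established. The spike-in controls (BioB, BioC, BioDn and CreX) were also brighter in replicate 3 than in replicate 1, by 1.51-fold on U74Av2, 1.36-fold on U74Bv2 and 1.18-fold on U74Cv2 at the median. In replicate 2, however, they were dimmer than in replicate 1, at 0.92, 0.86 and 0.76-fold, while 18S was brighter, so the spike-in controls did not follow 18S. A difference between replicates in how much ribosomal RNA was carried into the labelled target is a candidate explanation that the files cannot test, and no biological explanation was tested.

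The excess of detected genes in 20 lists could come from the number of probe sets per gene and the array design. If these were the whole cause, almost none of the 20 lists would pass the adjusted threshold against lists matched on both, but 7 did. The matching counted probe sets per gene and design only up to a cap, so it was incomplete for genes with many probe sets. The 7 lists thus exceeded what this matching covers, and a part played by higher probe set numbers stays open. For the other 13, the median excess was 23.8 percentage points over other genes and 16 over matched random lists, so part of it went with probe set number and design, and the rest stays open. No biological explanation was tested, since there is one condition.

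The count of 63 shared control probe sets that differed between designs was reached by 5 of 100 splits of the 9 arrays into 3 groups, the real one included, and the highest other count was 66. This count by itself does not exclude chance. Each of the 4 other splits kept the U74Av2 arrays together and mixed those of U74Bv2 and U74Cv2, so they carry part of the same difference. A further test was chosen only after this count and the shifts between designs had been seen. In it, the medians of the arrays over the shared probe sets differed most between the real groups out of all 280 splits, an exact p of 0.00357, the smallest that this test can give. Design and scan day cannot be told apart.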
